A study of Medicago truncatula with 2 samples.

How the data were processed

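Small RNAs were sequenced from roots of Medicago truncatula Jemalong A17, the reference line of this model legume. One library came from roots inoculated with the arbuscular mycorrhizal fungus Glomus intraradices, strain BB-E, and 1 from roots without inoculum. Per the labels' protocols, plants grew in sand and expanded clay at 25 °C with 16 h of light, were fed half-strength Hoagland solution with 20 µM phosphate, and received inoculum at 10% of the substrate volume. The labels place the inoculated roots at 3 weeks after inoculation and give no time for the other roots. Total RNA was isolated with a small RNA kit (mirVana) and a plant RNA aid, and libraries were made with Illumina's Digital Gene Expression small RNA kit, per the labels' protocols.

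The deposited files hold raw counts, 1 row per distinct sequence (tag) of 15 to 31 nt, per the file headers and the values. The 3′ adapter had already been removed: its first 8 nt were found in 0.00736% of mycorrhizal and 0.00968% of non-mycorrhizal reads. The trimming tool, the length limits and any quality filter are not given in the sources used here. The files hold no genome match, no locus and no annotation, and no genome sequence was used here, so no tag carries a coordinate. The gene table at hand lists no microRNA (miRNA) genes and was not used.

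Normalised read counts (RPM) were computed by dividing the deposited counts by the library's reads of 18 to 30 nt, scaled to 1000000. These reads numbered 7738940 in the mycorrhizal and 7656019 in the non-mycorrhizal library. A list of 38 miRNA families (tasiR-ARF, a trans-acting siRNA, included) with 62 reference sequences, in 8 functional groups, was fixed before the data were examined. The reference sequences were written from general knowledge, so a count of 0 means that these sequences were not seen, not that the family was absent. A tag of 19 to 24 nt was assigned to a family when it held an 18-nt stretch of a reference sequence in register within 2 nt of its start. Near-identical genes of a family cannot be told apart by such tags.

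With 1 library per group there is no replicate check, no test between the conditions and no p-value. Each RPM ratio is mycorrhizal over non-mycorrhizal and is given with the exact conditional binomial (Clopper-Pearson) 95% interval; shares have exact Clopper-Pearson intervals. Reads are PCR copies without molecular identifiers, so intervals and floors cover counting error only. A family was counted as at least 2-fold higher or lower when it had 100 or more reads over both libraries, a ratio of 2 or more or of 0.5 or less, and an interval that excluded 1. For tags of 20 to 24 nt outside the list the limit was 4-fold. A ratio against 0 reads was computed against a floor of 3 reads in that library, which is 0.388 RPM in the mycorrhizal and 0.392 RPM in the non-mycorrhizal library.

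Each functional group is described by the median log2 ratio of its families with 100 or more reads. This median was placed among those of 10000 random lists of 20 to 22 nt tags. Each family had 100 matched tags, those nearest to it in mean expression, with 0.5 reads added to each tag's counts. Single tags were thus set against families summed over tags. For abundant families the match was loose. The matched tags of miR1507 and miR166 had the same lower and upper limits of log2 ratio, -1.84 and 0.81, though miR166 was far more abundant. Percentiles of abundant families therefore rest on largely the same tags. The matched tags had 20 or more reads. They can include fungal RNA and fragments of ribosomal or transfer RNA, since no genome separated these. Fungal ribosomal RNA was counted as tags that shared a 16-mer, on either strand, with 1 of 7 primers for arbuscular mycorrhizal fungi, written from general knowledge before the data were examined.

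The names given were set by a rule fixed before the data were examined: every listed family with 100 or more reads and the 5 star strands with the largest fold difference among those with 100 or more reads. Families under 100 reads are summarised, the low ones of the nutrient groups by name. Members of families and star strands named outside the 5 were chosen after their values were seen. The rule also covered the most different and the most abundant tags with a match to the plant genome; without a genome this part could not be applied, and no such tag is named. The planned restriction of the 4-fold count to tags matching the genome outside structural RNA could not be applied either, nor could the shares of reads matching the genome or structural RNA be computed.

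Star strands, the strands paired with a miRNA in its precursor, were to be found by folding the loci. In place of this, tags of 20 to 22 nt with 50 or more reads were searched for pairing with 33 reference sequences with 20 or more reads. This search was designed after the counts had been seen. A first form, with overhangs of 1 to 3 nt, GU pairs at no penalty and a limit of 4 unpaired bases, paired 266 tags, against a mean of 193.1 with 20 sets of shuffled references. The search was then restricted to 2-nt 3′ overhangs, a penalty of 0.5 per GU pair and a limit of 3. This paired 19 tags, against a mean of 0.1 with shuffled references, and is the form reported. Limits of 3.5, 4 and 4.5 were also run, the limit of 4 for a time as the reported form, before the limit of 3 was restored. These limits change which star strands are included, as described under the dependence on processing.

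Other choices were also made after the data had been seen. Tags sharing 12 nt with the 5′ adapter were left out of tag lists but not out of the denominator. A minimum of 30 reads was set for tags found in 1 library only, and single members were described from 1000 reads. Exceptions were those of miR169, the tasiR-ARF reference sequence, and the miR172, miR396 and miR399 members paired with described stars. The fungal markers were also summed without the primer AML1, family tags with up to 2 mismatches and denominators without adapter reads or over tags found in both libraries were tried, and ratios were divided by the median ratio of tags of the same GC content.

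Scaling factors were computed with edgeR 4.0.16 (TMM) and DESeq2 1.42.0 (median of ratios) in R 4.3.3 over 32769 tags with 10 or more reads in each library, as alternatives to total counts. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The 4-fold count was tested on simulated data for 4119 tags. It recovered 50 of 50 tags set 6-fold higher, 49 of 50 set 6-fold lower and 50 of 50 set 10-fold either way, and called 0 of 3919 unchanged tags. The simulation held counting error only and says nothing of variation between plants. No tag was set to a fold between unchanged and 6-fold, so calls near the 4-fold limit were not tested.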

Results

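Small RNA profiles were compared between 1 library from mycorrhizal and 1 library from non-mycorrhizal roots of Medicago truncatula. The deposited counts summed to 8187981 reads of 3878418 distinct tags in the mycorrhizal library and 8350029 reads of 3798457 tags in the non-mycorrhizal library. Of 6771528 tags over both libraries, 905347 were found in both, and these held 56.9% of mycorrhizal and 61.4% of non-mycorrhizal reads. Tags seen once made up 81.2% and 81.7% of the tags. There were no replicates, so each difference is between these 2 libraries and its interval covers counting error alone. Tags with 5′ adapter sequence held 1.35% of mycorrhizal and 3.73% of non-mycorrhizal reads, and reads of 15 to 17 nt held 5.48% and 8.30%.

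The first comparison concerned the size classes of small RNA. Both libraries were dominated by 24-nt reads, the size of heterochromatic siRNAs in plants, followed by 21-nt reads, the size of most miRNAs. The 24-nt class held 55.3% of mycorrhizal and 55.2% of non-mycorrhizal reads of 18 to 30 nt. The 21-nt class held 15.8% and 15.3%, the 22-nt class 5.63% and 5.27%, and the 23-nt class 7.86% and 7.60%. Of the 21-nt reads, 65.4% in the mycorrhizal and 63.3% in the non-mycorrhizal library began with T. Without reads carrying 5′ adapter sequence the 24-nt share was 55.8% in the mycorrhizal and 57.1% in the non-mycorrhizal library.

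**Figure D1:**
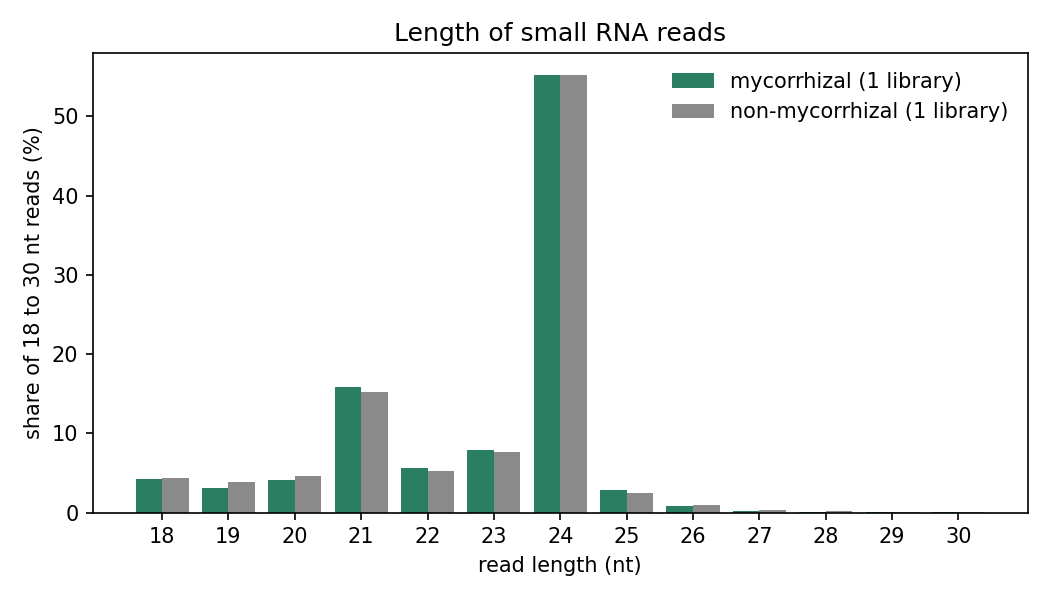
Share of 18 to 30 nt reads (%, y axis) at each read length in nt (x axis), 1 bar per library. The 24-nt class stands at 55.3% in the mycorrhizal and 55.2% in the non-mycorrhizal library, and the 21-nt class at 15.8% and 15.3%.

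Ribosomal RNA markers of the fungus were counted as a check of the labels. Of 7 primers written down for arbuscular mycorrhizal fungi, FLR4 matched 456 reads, FLR2 109, FLR3 65, AM1 24 and AML2 2 in the mycorrhizal library, and each of these 5 matched 0 reads in the non-mycorrhizal library. GLOM1310 matched 0 reads in either library. AML1 matched 633 mycorrhizal and 556 non-mycorrhizal reads, a ratio of 1.13 (95% interval 1.00 to 1.26). Whether AML1 also matches plant ribosomal RNA was not checked. All 7 primers together matched 1284 and 556 reads, a ratio of 2.28 (2.07 to 2.53), which includes the reads of AML1. Without AML1, a sum formed after its values were seen, the counts were 651 and 0. This was 214.675-fold higher in the mycorrhizal library against the floor of 3 reads, with an exact lower 95% limit of 174 for the ratio. With a shared 20-mer that sum was 109 and 0 reads, 35.9-fold higher against that floor, with a lower limit of 28.7.

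The main comparison asked which miRNA families differed between mycorrhizal and non-mycorrhizal roots. Among 24 families with 100 or more reads, 2 were at least 2-fold higher in the mycorrhizal library and 0 at least 2-fold lower. The first was miR171h, which targets the GRAS transcription factor NSP2 of symbiotic signalling. It stood at 395 RPM in the mycorrhizal and 182 RPM in the non-mycorrhizal library, from 3060 and 1392 reads, a ratio of 2.17 (2.04 to 2.32). This ratio lay above those of all 100 single tags nearest to it in mean expression. Its reference sequence CGAGCCGAATCAATATCACTC held 2830 and 1285 of these reads.

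The second was miR169, which targets NF-YA transcription factors, among them a regulator of nodule development. It had 92 reads in the mycorrhizal and 16 in the non-mycorrhizal library, 11.9 and 2.09 RPM, a ratio of 5.69 (3.32 to 10.4). This was at the 94th percentile of its 100 matched tags, so some of those differed more. Its 108 reads only just passed the minimum of 100, and counting exact reference sequences alone left it under that minimum. Of its members, AAGCCAAGGATGACTTGCCGG had 52 against 3 reads, a ratio of 17.1 (5.55 to 85.8), and CAGCCAAGGATGACTTGCCGG 18 against 7, a ratio of 2.54 (1.01 to 7.21). CAGCCAAGGATGACTTGCCGA had 6 against 4, a ratio of 1.48 (0.352 to 7.15). The first member thus held 52 of the family's 92 mycorrhizal reads and had the highest ratio of these reference sequences. The family's other tags were not described singly.

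Together the listed families held 503465 mycorrhizal reads, 6.51% of those of 18 to 30 nt, and 456941 non-mycorrhizal reads, 5.97%. The median ratio of the 24 families was 1.10. The interval lay above 1 for 15 families, below 1 for 6 and included 1 for 3.

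**Figure D2:**
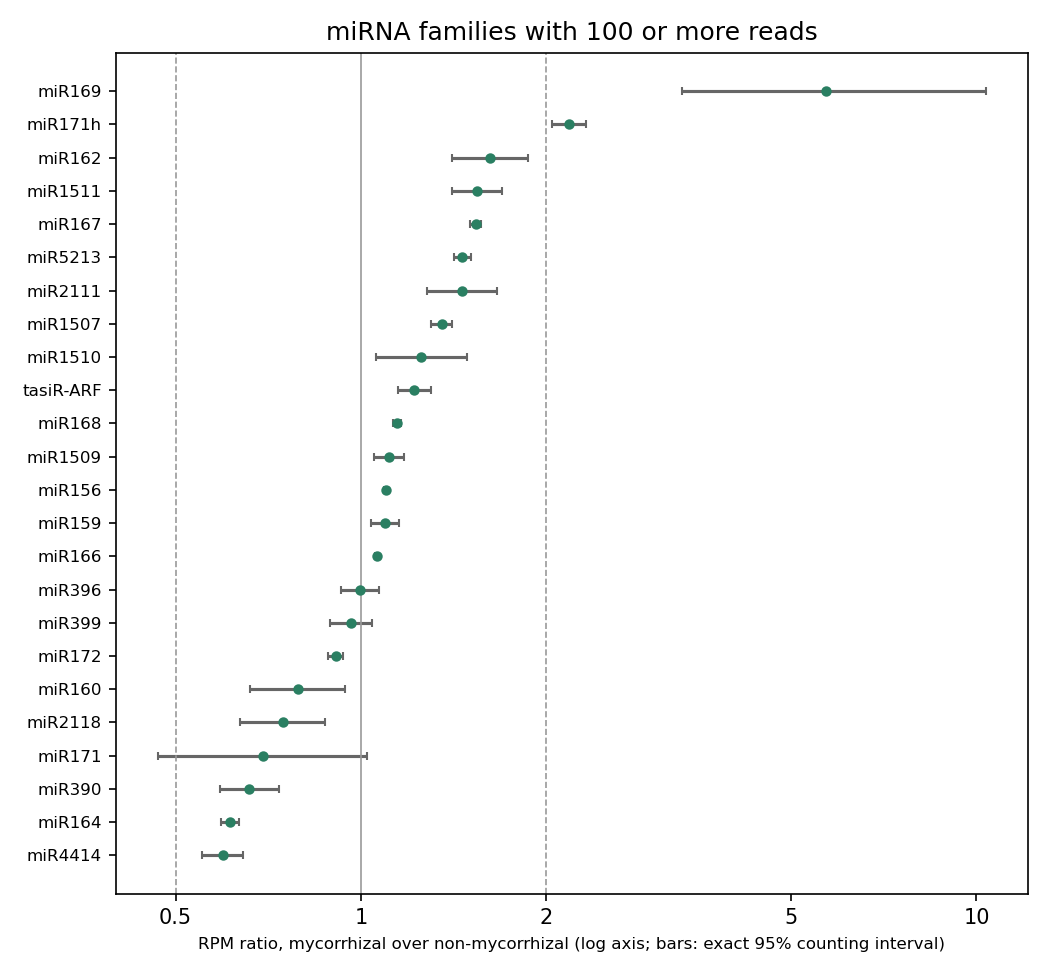
Ratio of RPM, mycorrhizal over non-mycorrhizal (x axis, log scale), for the 24 miRNA families with 100 or more reads (y axis), 1 library per group. Points are ratios, bars exact 95% counting intervals, the solid line 1 and the dashed lines 2-fold either way. miR169 at 5.69 and miR171h at 2.17 lie beyond 2-fold, and miR4414 is lowest at 0.596.

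In the group of symbiosis families, miR171h and miR169 were higher in the mycorrhizal library, while miR171, which targets other GRAS factors, had 47 against 67 reads, a ratio of 0.694 (0.468 to 1.02). The median log2 ratio of these 3 families was 1.12, at the 99.6th percentile of random lists. As the middle of 3 values it was that of miR171h itself, so the group adds no evidence beyond that family. With exact reference sequences, which left 2 families, the group's median was 0.35. With up to 2 mismatches allowed, the ratio of miR171 was 1.07.

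The auxin families went both ways. miR167, which targets the auxin response factors ARF6 and ARF8, stood at 2978 against 1938 RPM, a ratio of 1.54 (1.51 to 1.57), and tasiR-ARF, which targets ARF3 and ARF4, at a ratio of 1.22 (1.15 to 1.30). miR164, which targets NAC transcription factors, was lower in the mycorrhizal library at 711 against 1161 RPM, a ratio of 0.612 (0.592 to 0.633). miR390, which triggers the production of tasiR-ARF, was at 0.659 (0.590 to 0.736), and miR160, which targets ARF10, ARF16 and ARF17, at 0.790 (0.661 to 0.943). The group's median log2 ratio was -0.34, at the 17.5th percentile. GC-rich tags were lower in the mycorrhizal library as a class: across 3856 tags of 20 to 24 nt outside the list, which are not independent replicates, GC content and log2 ratio had a Spearman rho of -0.388. Division by the median ratio of tags of the same GC content turned the group's median to 0.13, put miR160 at 1.09 (0.916 to 1.31), and gave 0.849 (0.821 to 0.879) for miR164 and 0.912 (0.816 to 1.02) for miR390, an interval that includes 1. With up to 2 mismatches allowed, miR160 turned to 1.22 (1.05 to 1.42) and the group's median to 0.29.

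Both measured families of the small RNA machinery were higher in the mycorrhizal library. miR162, which targets DCL1, had a ratio of 1.62 (1.41 to 1.87), and miR168, which targets AGO1, stood at 5382 against 4698 RPM, a ratio of 1.15 (1.13 to 1.16). Their median log2 ratio was 0.45, at the 87.5th percentile. Of the families that target NBS-LRR resistance genes, 3 of 4 were above a ratio of 1: miR5213 at 1.46 (1.42 to 1.51), miR1507 at 1.35 (1.30 to 1.41) and miR1510 at 1.25 (1.06 to 1.49). The other, miR2118, was at 0.747 (0.637 to 0.874). With up to 2 mismatches allowed it was at 0.897 (0.784 to 1.03), an interval that includes 1. The group's median log2 ratio was 0.38, at the 88.4th percentile.

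Of the phosphate and sulfate families, 2 of 4 had 100 or more reads. miR399, which targets the phosphate regulator PHO2, stood at 161 against 167 RPM, a ratio of 0.963 (0.890 to 1.04); this direction turned when mismatches were allowed (1.09), over tags found in both libraries (1.03) and after the GC correction (1.16). miR2111, which targets F-box genes, was higher in the mycorrhizal library at 74.7 against 51.2 RPM, a ratio of 1.46 (1.28 to 1.66). The median of these 2 was a log2 ratio of 0.25, at the 77.2nd percentile. The phosphate and sulfate family miR395 had 0 against 4 reads and miR827 0 in both libraries, and no listed copper family (miR397, miR398, miR408, miR2119) had more than 4 reads over both libraries.

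In the development group, 3 of 5 families were above a ratio of 1 and 2 below. miR166, which targets class III HD-ZIP factors, was the most abundant family at 36594 against 34487 RPM, a ratio of 1.06 (1.06 to 1.07), and 0.944 with exact reference sequences or 1.38 after the GC correction. miR156, which targets SPL factors, had a ratio of 1.10 (1.09 to 1.11), miR159, which targets MYB factors, 1.10 (1.04 to 1.15), and miR172, which targets AP2 factors, 0.910 (0.884 to 0.936). miR396, which targets growth-regulating factors, stood at 0.998 (0.929 to 1.07), no difference being detectable at this depth. The group's median log2 ratio was 0.09, at the 50.7th percentile. Of the other families, miR1511 had a ratio of 1.54 (1.41 to 1.69), miR1509 1.11 (1.05 to 1.18) and miR4414 0.596 (0.553 to 0.643), with a median log2 ratio of 0.15 at the 66.6th percentile. That median was -0.0428 with exact reference sequences, which left 2 of the families, and 0.0115 after the GC correction, which put miR1509 at 1.01 (0.953 to 1.07). Another 14 listed families had under 100 reads over both libraries, 60 at most, and 7 of these had 0.

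Members of 1 family did not always share its ratio. In miR156 the 20-nt TGACAGAAGAGAGTGAGCAC was at 0.999 (0.989 to 1.01), while TTGACAGAAGATAGAGAGCAC was at 1.60 (1.57 to 1.63). In miR167, TGAAGCTGCCAGCATGATCTA was at 2.10 (2.02 to 2.19) and TGAAGCTGCCAGCATGATCTG at 1.39 (1.33 to 1.46). In miR166, TCGGACCAGGCTTCATTCCCC was at 0.944 (0.937 to 0.9499), while the most abundant form starting 2 nt upstream was at 1.74 (1.71 to 1.76). These members were chosen after their values were seen.

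Star strands were compared with the miRNAs by the pairing search, which was designed after the counts were seen. It gave 13 candidates with 100 or more reads in 7 families, and 0 were at least 2-fold higher or lower. The 5 with the largest difference were 2 miR172 stars at 1.83 (1.30 to 2.61) and 1.65 (1.36 to 1.997), 2 miR2111 stars at 1.72 (1.19 to 2.49) and 1.66 (1.28 to 2.16), and a miR399 star at 0.616 (0.457 to 0.827). The miR172 star at 1.83 pairs with AGAATCCTGATGATGCTGCAG, itself at 1.39 (1.07 to 1.81). The miR172 star at 1.65 pairs with AGAATCTTGATGATGCTGCAT, which was at 0.899 (0.873 to 0.927). A candidate miR169 star was included only at looser pairing limits, from 3.5, and was at least 2-fold higher there.

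Outside the list, 4005 tags of 20 to 24 nt had 100 or more reads. Of these, 191 were at least 4-fold higher and 69 at least 4-fold lower in the mycorrhizal library. Among the higher tags 148 had 0 reads in the non-mycorrhizal library, 64.9% began with T and 94 were of 24 nt. The lower tags had a mean GC content of 60.2%, against 48.8% over all 4005, and 14.5% began with T. No genome separated plant from fungal tags or removed structural RNA. With a minimum of 20 reads there were 1822 higher and 641 lower tags of 39002, and the GC correction gave 191 higher and 40 lower, 38 of them among the 69. The 148 higher tags with 0 non-mycorrhizal reads could not be lost under that correction, so the unchanged 191 says little of GC content.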

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

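The tests on these tags were chosen after the tags had been seen. Tags with 30 or more reads in 1 library and none in the other were not compared above as a class, although those of 20 to 24 nt with 100 or more reads are among the tags at least 4-fold different. Their number in the mycorrhizal library stood far above that in the control. The mycorrhizal library had 1284 such tags with 97948 reads, 1.20% of its total, and the non-mycorrhizal library 12 with 703 reads. Sampling of tags present at equal rates is argued against, since the totals of 28386 tags with 30 or more reads over both libraries would give 2.43e-06 tags found in the mycorrhizal library alone, by counting error only. The cut of 30 reads against none makes such a number small in any 2 libraries of similar depth. It therefore bears on counting error and on no other source of difference. Of the 1284, 827 (64.4%) were of 23 to 25 nt, and 79.9% (95% interval 77.0 to 82.6) of those began with T. T made up 22.6% of their other positions, which argues against breakdown products without base preference for this size range. The 70 tags of that size that matched the 6 primers other than AML1 began with T in 44.3% (32.4 to 56.7). Tags at a few ribosomal sites can thus also start with T more often than 22.6%, though less often than 79.9%. Only 21.005% of tags of that size found in both libraries with 30 or more reads over both began with T, which argues against small RNAs of that kind. The intervals of these shares count tags as independent draws, although tags are not independent replicates.

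What stays open is whose RNA these tags are. RNA of the fungus is a candidate explanation, since fungal ribosomal markers other than AML1 gave 651 reads in this library and none in the other. Only 1 of the 1284 tags itself matched any of the 7 primers, which cover short sites, so the markers show fungal RNA in the library and not the origin of these tags. Plant small RNAs made only in colonised roots are another candidate for the 827 tags. The 2 cannot be told apart here, since no genome of the plant or the fungus was searched. Variation between plants or library preparations also stays open with 1 library per group, so a link of these tags to colonisation was not tested.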

How the results depend on the processing

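Adapter reads, shared tags, mismatches, GC content, the sum without AML1 and all star pairing limits were tried after seeing the data; the others were planned. Of 237 ratios of 24 families under 10 alternatives, 190 stayed within their counting interval, 47 moved and 0 of the called families reversed. Staying within depends on interval width: miR169, with few reads, did so in 9 of 9 alternatives, and abundant miR166 in 2 of 10. Reversal was counted for the called families only. Of those not called, miR160, miR166, miR171, miR396 and miR399 crossed a ratio of 1 under at least 1 alternative. The alternative minimum of 20 reads could not change the ratio or the call of a family that passed the main minimum. The ratios of the 24 families under that alternative are among the 190 for this reason alone and say nothing of stability. Scaling shifted all log2 ratios by 0.10 at most. miR171h was called under every alternative and miR169 under all but exact reference sequences, which left 1 family higher because miR169 had too few reads; 0 were lower under each. miR160 and miR171 moved over 1.5 times, to 1.22 and 1.07 with mismatches. Where no cause is named below, the cause was not tested.

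For development, with a very narrow interval, the median log2 ratio was 0.0732 over 20 to 24 nt, 0.13 over all reads, 0.10 by median of ratios, 0.12 by TMM, 0.0510 without adapter reads, 0.18 over shared tags, 0.0503 with exact sequences, 0.0411 at 20 reads, 0.0362 with mismatches and 0.0774 after GC correction. GC correction gave 0.13 for auxin, 0.0115 for other and 0.70 for small RNA machinery. Mismatches gave 0.29 for auxin. Shared tags gave 0.25 for other and 1.22 for symbiosis. Exact sequences gave -0.0428 for other and 0.35 for symbiosis, with fewer families.

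Tags at least 4-fold higher and lower numbered 1822 and 641 at 20 reads and 10935 and 4941 with no minimum, because more tags were tested; GC correction gave 40 lower. The fungal marker ratio was 1.93 with 20-mers and 2.001 over all reads. Without AML1 the ratio against the floor of 3 reads was 214.675, or 35.9 with 20-mers. The exact lower limits were 174 and 28.7. In the mycorrhizal library the 21-nt share was 6.26% of distinct tags and 15.6% without adapter reads, and the 24-nt share 68.1% and 55.8%; in the other library they were 5.68% and 14.2%, and 70.1% and 57.1%.

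Star strands at least 2-fold different numbered 0 at the reported limit of 3, 2 with the exact start (miR2111 at 2.01, miR399 at 0.459 from 26 and 56 reads; the 100-read minimum applied to all starts together), 1 at each limit of 3.5, 4 and 4.5, and 16 in the first form, which paired 266 tags against 193.1 with shuffled references. The 1 at looser limits is a candidate miR169 star with 217 against 13 reads, a ratio of 16.5 (9.46 to 31.5), chosen after its values were seen. At 3.5 the search paired 22 tags against 0.15 with shuffled references, at 4 28 against 0.7 and at 4.5 36 against 2.25.

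Not run without a genome: denominators and length shares of genome-matched reads, the 1-mismatch genome match and structural RNA. No paired analysis was possible because each group had 1 library. Depth limits families under 100 reads: the floor of 3 reads used for a count of 0 is 0.388 RPM in the mycorrhizal library.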

Other observations

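The test of scaling and those left open for lack of replicates or sequences were chosen after the ratios had been seen; those of GC content were set before the corrected values were known. The members of 1 miRNA family and its star strands gave different ratios in several cases, picked outside the rule for names after their values were seen. The second miR396 star candidate was at 1.56 (1.43 to 1.70), where the family was at 0.998 and the first star candidate at 0.961 (0.915 to 1.01). Both pair with a reference sequence at 1.21 (0.884 to 1.66), from 93 and 76 reads, an interval that overlaps those of both. The first candidate had 3230 and 3325 reads, above the family's 1547 and 1534. The 3 miR399 star candidates were at 0.836, 0.616 and 0.623, with the family at 0.963. The first pairs with a reference sequence at 0.876 (0.687 to 1.12), an interval that includes 0.836. The others pair with another reference sequence, at 1.11 (0.936 to 1.31). The form of miR166 that starts 2 nt upstream held 46294 mycorrhizal and 26376 non-mycorrhizal reads.

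That miR171h and miR169 were at least 2-fold higher was weighed against 2 technical explanations. Scaling between libraries is argued against by the lowest ratio of either family over 6 other scalings, 2.12. GC content is argued against by the lower of the 2 corrected ratios, 2.23. Variation between plants or library preparations stays open with 1 library per group, so a response of these families to colonisation is a hypothesis that these data could not decide.

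The 69 tags at least 4-fold lower in the mycorrhizal library were GC-rich, at a mean of 60.2%. The median log2 ratio of the 3856 tags of 20 to 24 nt outside the list with 100 or more reads, and reads in both libraries, was lower at higher GC content, from 0.20 at 30 to 35% GC to -0.48 at 60 to 65%. After GC correction 38 of the 69, 55.1% (95% interval 42.6 to 67.1), stayed at least 4-fold lower, an interval that includes 50%, so the part of GC bias could not be settled. That interval counts the 69 tags as independent draws, although tags are not independent replicates. The tags that set the correction also included most of the 69. More ribosomal and transfer RNA fragments in the non-mycorrhizal library may also account for the 60.2%; no such sequences were searched.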
